A study of Homo sapiens with 21 samples.

How the data were processed

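RNA of 22Rv1 cells was captured by poly(A) tail and sequenced as paired-end reads of 150 bp, per the labels' protocols. Reads were trimmed with Trim Galore, aligned with STAR to hg38 and counted on genes with HTSeq, per the labels, and the versions and the strand setting are not given in the sources used here. The deposited values are raw gene counts as the authors' counting step wrote them, with no normalization, 1 table per library. Each table held 58721 genes and 5 lines for reads that were counted on no gene, which took 25.7% to 35.0% of the counted total in the deletion experiment and 27.2% to 32.1% in the siRNA experiment and were left out of library sizes and tests. The gene identifiers were those of GENCODE release 29, and 99.2% (58252) matched a current symbol. ChIP-seq, ATAC-seq and Region Capture Micro-C, named by the series, are not used here.

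The 21 libraries were grouped by their labels into 7 groups of 3. The deletion experiment (12 libraries) and the siRNA experiment (9 libraries) were fitted separately, because no group is shared between them. In each, genes passed the filterByExpr filter of edgeR, which kept 18109 and 17399 genes. Library sizes were scaled by the trimmed mean of M values (TMM), and groups were compared by 2-sided quasi-likelihood tests in edgeR 4.0.16 under R 4.3.3. P-values were adjusted by Benjamini-Hochberg over the genes of each comparison with a threshold of 0.05. CPM values use the TMM-scaled library sizes. The 9 comparisons were each group against its control (5) and the perturbed groups of an experiment against each other (4). The median log2 fold change of all genes moved by less than 0.03 between TMM and the size factors of DESeq2. A gene at 0 counts in a group was given a bound from a floor of 3 counts over the group, and a gene with 1 to 3 counts the ratio of counts scaled by library size with an exact 95% interval. These bounds cover counting error only.

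The 33 gene lists (812 symbols, 809 found) stood for the biology of prostate cells, stress, metabolism and proliferation, for other cell types (basal, fibroblast, endothelial, immune) and for RNA quality or capture (mitochondrially encoded, ribosomal protein and replication-dependent histone genes). The 31 lists with at least 5 measured genes were tested with camera of limma 3.58.1 at its preset correlation of 0.01, again with an estimated correlation, and with fry, and adjusted over the 31 lists. Fry, which asks only whether the genes of a list move one way on balance, called 27, 23 and 20 lists in cPCE_del, rPCE_del and resPCE_del against NTC. For each comparison with a control, the genes named were the members of the list of genes around HEBP2 and NHSL1 and up to 4 members of each list with the smallest adjusted p. Added to these were the 10 largest rises and 10 largest falls among protein-coding genes with an adjusted p under 0.05, a mean of at least 1 CPM and no overlap between the libraries of the groups (10% of genes do not overlap by chance for 3 against 3). For the other comparisons the members of that list and 5 genes in each direction were named. Some genes that this rule selects are not reported here. The groups, comparisons, lists, this rule and the alternatives not named below as added were set before the data were examined.

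The steps were tested on simulated counts with 200 changed genes, picked among genes above a minimum expected count. The simulated sets held no library that stood apart. For cPCE_del against NTC (16854 genes) 41.8% of 1.5-fold, 89.6% of 2-fold and 100% of 4-fold changes were recovered, for siHEBP2 against siNTControl 61.2%, 85.1% and 100%, and for siNHSL1 against siNTControl 61.2%, 92.5% and 100%. Unchanged genes made up 4.76%, 7.43% and 7.84% of the calls. The alternatives were DESeq2 1.42.0, its size factors in edgeR, no filter on low counts, a filter of at least 50 counts in 3 libraries, the replicate number as a block, fits of the 6 libraries of a comparison or of all 21, an estimated correlation in camera, and each library left out in turn. Added after the data were seen were scaling by library size alone, counts thinned to the smallest total, removal of a trend on exon length, and fits without siNHSL1 replicate 3 or rPCE_del replicate 1. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.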

Results

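RNA was sequenced from 22Rv1, an established human prostate cancer cell line, in a deletion experiment and an siRNA experiment. The deletion experiment held NTC, a control by its label, and cells with deletions labelled cPCE_del, rPCE_del and resPCE_del, with 3 libraries in each of these 4 groups. The siRNA experiment held siNTControl, siHEBP2 and siNHSL1, with 3 libraries each. The series title names chromatin architecture and enhancer classes in prostate cancer, but the labels used here neither spell out these group names nor give the positions of the deleted elements, and they do not say whether the deletion cells are clones or pools. Each library was a table of reads counted on genes. The total counts per library were 25704102 to 34801578 in NTC, 10123490 to 18917342 in cPCE_del, 13535447 to 16644089 in rPCE_del and 30595625 to 36065470 in resPCE_del. They were 14853292 to 16932155 in siNTControl, 15832002 to 18219948 in siHEBP2 and 15869952 to 17034175 in siNHSL1. Levels are CPM, the usual scaling of counts to library size, as mean ± SD, n = 3 libraries in every group, and fold changes are log2 ± SE from edgeR. Medians and means of gene lists are of log2 fold changes. A setting that removed the trend on exon length was added after the data were seen. The labels describe 3 RNA replicates per condition without saying whether they came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

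HEBP2, which encodes a heme-binding protein, and NHSL1, which encodes a regulator of lamellipodia and cell migration, are the genes named by the siRNAs. HEBP2 (ENSG00000051620.10) lies on chromosome 6 at 138403531 to 138422197 of hg38 on the plus strand. NHSL1 (ENSG00000135540.11) lies at 138422043 to 138692571 on the minus strand. The ends of the 2 genes overlap and the strand setting of the counting is not given, so the assignment of reads in the overlap is uncertain. With siHEBP2, HEBP2 fell from 128 ± 10.7 to 56.4 ± 10.6 CPM (log2 fold change -1.18 ± 0.13, adjusted p = 0.00330), while NHSL1 was 31.4 ± 1.73 against 31.1 ± 2.90 CPM in the control (adjusted p = 0.996). With siNHSL1, NHSL1 was 13.2 ± 4.93 against 31.1 ± 2.90 CPM in the control and did not pass the test (log2 fold change -1.23 ± 0.20, adjusted p = 0.104). HEBP2 there was 139.8 ± 18.2 against 128 ± 10.7 CPM (adjusted p = 0.705). The HEBP2 call was lost without siNTControl replicate 1 (adjusted p = 0.0806), siNTControl replicate 3 (adjusted p = 0.0581) or siHEBP2 replicate 2 (adjusted p = 0.0840). NHSL1 passed the test without siNHSL1 replicate 3 (log2 fold change -0.95, adjusted p = 1.08e-06), without siNHSL1 replicate 1 (adjusted p = 0.0461), with DESeq2 (adjusted p = 1.47e-05) and with the length trend removed (adjusted p = 0.0271).

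In the deletion experiment HEBP2 fell from 124 ± 5.89 to 44.5 ± 2.56 CPM in cPCE_del (log2 fold change -1.48 ± 0.083, adjusted p = 6.29e-09). It fell to 49.3 ± 2.20 CPM in resPCE_del (log2 fold change -1.34 ± 0.082, adjusted p = 4.63e-08). In rPCE_del it rose to 154 ± 0.784 CPM (log2 fold change 0.31 ± 0.080, adjusted p = 0.00564). The 163 genes of the long arm of chromosome 6 up to HEBP2 had a median of 0.33 there, so this rise was no larger than that of its region. NHSL1 fell in all 3 deletion groups, from 55.2 ± 4.42 CPM in NTC to 15.2 ± 1.51 CPM in cPCE_del (log2 fold change -1.85 ± 0.17, adjusted p = 7.06e-07). It was 33.5 ± 8.63 CPM in rPCE_del (log2 fold change -0.72 ± 0.16, adjusted p = 0.00183) and 12.9 ± 0.525 CPM in resPCE_del (log2 fold change -2.10 ± 0.16, adjusted p = 4.22e-07). In rPCE_del, NHSL1 was 23.6 CPM in replicate 1, which stood apart from its group, and 39.1 and 37.9 CPM in replicates 2 and 3. These lay below every NTC library (lowest 50.4 CPM), but siNTControl, the control of the other experiment, had 28.4 to 34.1 CPM. The direct comparisons placed HEBP2 below rPCE_del in both cPCE_del (log2 fold change -1.79 ± 0.084, adjusted p = 1.37e-09) and resPCE_del, where rPCE_del exceeded resPCE_del by 1.64 ± 0.083 (adjusted p = 3.88e-09). Between cPCE_del and resPCE_del neither HEBP2 (log2 fold change -0.15 ± 0.082, adjusted p = 0.149) nor NHSL1 (log2 fold change 0.25 ± 0.17, adjusted p = 0.227) passed the test. These genes lie in stretches of chromosome 6 whose other genes also differed between groups, as given after the comparisons.

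**Figure D1:**
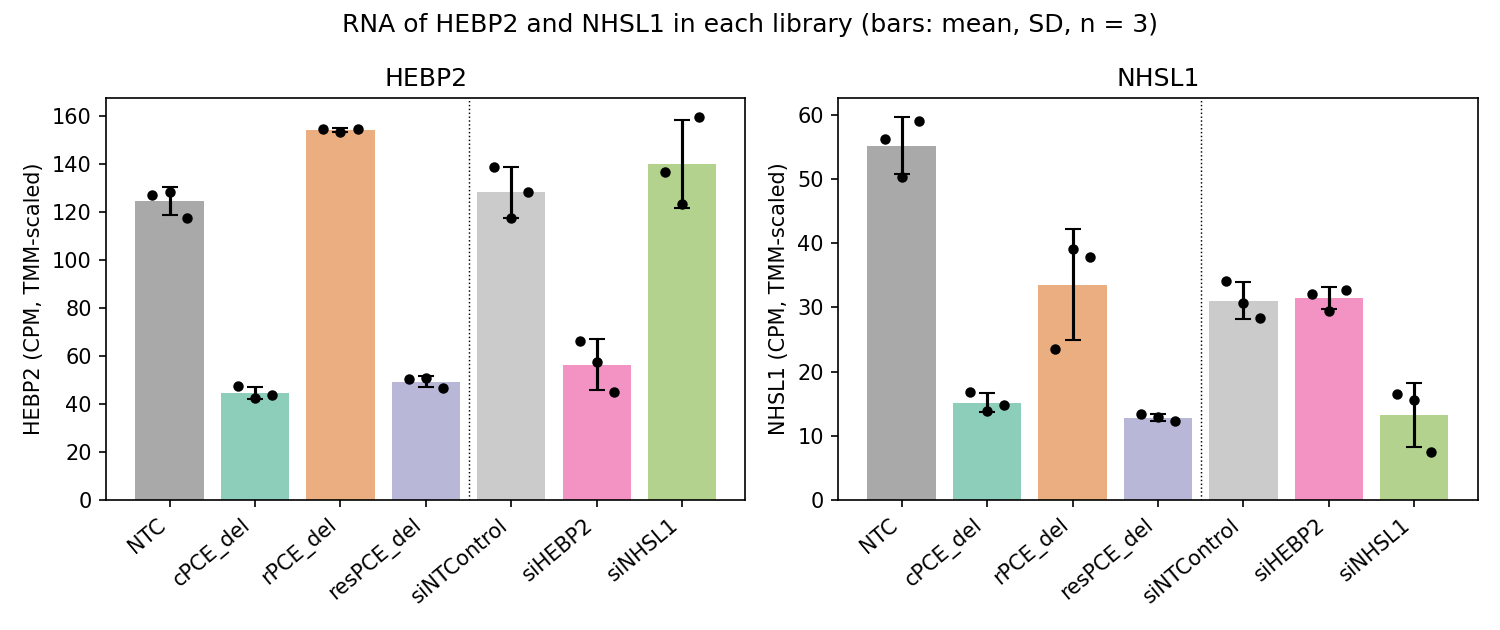
Level of HEBP2 and NHSL1 in each library, in CPM on a linear axis from 0, with 1 point per library and a bar for the mean with its SD of 3 libraries per group. HEBP2 was lower in cPCE_del (44.5 CPM) and resPCE_del (49.3 CPM) than in NTC (124 CPM), and higher in rPCE_del (154 CPM).

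The libraries of the deletion experiment fell into their 4 groups in a principal component analysis. The first component (43.8% of the variance) set cPCE_del apart from the rest and the second (32.4%) set rPCE_del apart. In the siRNA experiment the first component (27.4%) set siNHSL1 replicate 3 apart from the other 8 libraries.

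**Figure D2:**
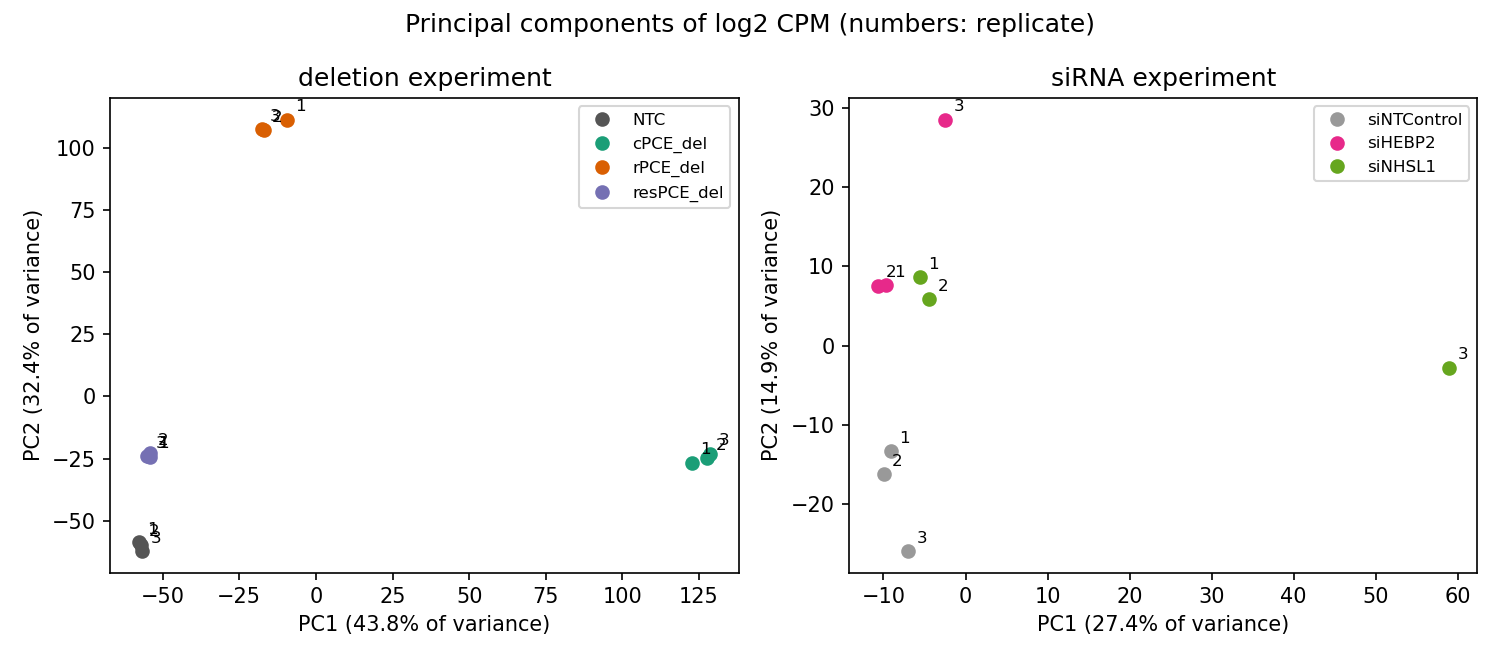
Principal components 1 and 2 of log2 CPM for the 12 libraries of the deletion experiment and the 9 of the siRNA experiment, with 1 point per library coloured by group and axes labelled with the percent of variance. The deletion groups separated from each other and from NTC, and siNHSL1 replicate 3 lay apart from the other siRNA libraries.

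The comparison of cPCE_del with NTC asks which genes differ in cells with this deletion. The neural splicing factor SRRM4 fell from 178 ± 7.73 to 0.0371 ± 0.0642 CPM, with 2 counts left in the 3 deletion libraries (ratio 3626, counting interval 1004 to 29945). LAMB3, a chain of the laminin of epithelial basement membranes, rose from 0.797 ± 0.358 to 349.7 ± 21.3 CPM (adjusted p = 8.56e-12). Fibronectin (FN1), a protein of the extracellular matrix, rose from 19.6 ± 5.15 to 1598 ± 57.1 CPM (adjusted p = 4.71e-10). Genes of cholesterol synthesis, fatty acid synthesis and endoplasmic reticulum protein folding rose, and genes of DNA replication, steroid metabolism and the neuroendocrine state fell. Of the 31 gene lists large enough to test, camera called 12, none of which passed with an estimated correlation, where the adjusted p of these 12 ranged from 0.0698 to 0.767. Of the 18109 genes tested, 4816 were higher and 5407 lower in cPCE_del, of which 2274 and 2772 differed at least 2-fold.

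Among the 10 largest rises in cPCE_del were MSX2, a homeobox transcription factor, which had 0 counts in NTC and 210.0 ± 7.86 CPM in cPCE_del (at least 6711-fold higher). INHBA, a subunit of activin, was at 49.7 ± 5.97 CPM against 0 (at least 1589.5-fold higher), and at 6.09 CPM in siNTControl. The ephrin receptor EPHA4 rose from 0.144 ± 0.129 to 318 ± 15.7 CPM (adjusted p = 1.09e-10), and latexin (LXN), an inhibitor of carboxypeptidases, rose from 1.33 ± 0.572 to 2415 ± 123 CPM (adjusted p = 6.47e-12). Among the 10 largest falls, UGT2B15, which conjugates androgens, went from 166 ± 4.08 CPM to 0 counts (at least 2263-fold lower). The chemokine CX3CL1 went from 57.1 ± 0.189 CPM to 0 (at least 779.6-fold lower). The growth factor gene BMP2 fell from 259.5 ± 8.87 to 0.0185 ± 0.0321 CPM with 1 count left (ratio 10602, counting interval 1903 to 418764). There were 61 genes at 5 CPM or more in NTC with at most 3 counts over the cPCE_del libraries, and 21 genes the other way round. In siNTControl, 57 of the 61 and 3 of the 21 were at 1 CPM or more.

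The androgen response list had 13 genes that rose and 17 that fell among 38 measured (13 up and 18 down adjusted over the list alone), and with the replicate number as a block its adjusted p was 0.160. In cPCE_del the androgen response list had a median of -0.27 (camera adjusted p = 0.00799, and adjusted p = 0.0698 with an estimated correlation). The prostaglandin-degrading enzyme HPGD fell from 206 ± 11.6 to 5.78 ± 0.567 CPM and the prostate transporter SLC45A3 fell from 87.7 ± 5.30 to 6.17 ± 0.340 CPM. The protease gene TMPRSS2 rose from 36.00 ± 2.69 to 153 ± 10.9 CPM. In the steroid metabolism list 2 of 15 rose and 9 fell (2 up and 9 down adjusted over the list alone), and the androgen-synthesising AKR1C3 went from 20.7 ± 0.904 CPM to 0 counts (at least 282-fold lower). In cPCE_del the steroid metabolism list had a median of -0.88 (camera adjusted p = 9.01e-05, and adjusted p = 0.0698 with an estimated correlation). Neuroendocrine markers fell in 8 of 13 and rose in 3 (3 up and 8 down adjusted over the list alone). In cPCE_del the neuroendocrine marker list had a median of -1.11 (camera adjusted p = 6.53e-04, and adjusted p = 0.0698 with an estimated correlation). The secretory granule protein SCG3 fell from 82.1 ± 6.81 to 0.396 ± 0.0963 CPM and synaptophysin (SYP) from 90.6 ± 3.24 to 11.7 ± 1.70 CPM. Of the 18 prostate luminal markers 7 rose and 7 fell (7 up and 7 down adjusted over the list alone, camera adjusted p = 0.475). AGR2, a protein folding enzyme of secretory epithelia, rose from 1.60 ± 0.310 to 307 ± 62.5 CPM, and FOLH1, the prostate-specific membrane antigen, rose from 221 ± 2.46 to 782 ± 50.9 CPM. Of 9 basal epithelial markers 3 rose and 3 fell (camera adjusted p = 0.0982).

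All 22 endoplasmic reticulum chaperone genes rose (22 up and 0 down adjusted over the list alone). In cPCE_del the endoplasmic reticulum chaperone list had a median of 1.15 (camera adjusted p = 4.10e-08, and adjusted p = 0.133 with an estimated correlation). XBP1, a transcription factor of the unfolded protein response, rose from 133 ± 5.17 to 871 ± 78.3 CPM and the chaperone HYOU1 from 354 ± 12.3 to 873 ± 40.3 CPM. Of 24 cholesterol synthesis genes 22 rose and 1 fell (22 up and 1 down adjusted over the list alone). In cPCE_del the cholesterol synthesis list had a median of 1.33 (camera adjusted p = 4.98e-07, and adjusted p = 0.121 with an estimated correlation). The methylsterol monooxygenase MSMO1 rose from 19.7 ± 5.88 to 208 ± 22.4 CPM and squalene epoxidase (SQLE) from 45.6 ± 6.996 to 154 ± 6.03 CPM. Fatty acid synthesis genes rose in 11 of 17 and fell in 3 (11 up and 3 down adjusted over the list alone). In cPCE_del the fatty acid synthesis list had a median of 0.72 (camera adjusted p = 0.00167, and adjusted p = 0.145 with an estimated correlation). The desaturase FADS2 rose from 44.7 ± 0.930 to 310.0 ± 17.2 CPM and ATP citrate lyase (ACLY) from 550.0 ± 15.5 to 2115 ± 124 CPM. Immediate early genes, which respond rapidly to growth factors and stress, rose in 12 of 16 and fell in 2 (12 up and 2 down adjusted over the list alone). In cPCE_del the immediate early list had a median of 1.25 (camera adjusted p = 4.54e-06, and adjusted p = 0.121 with an estimated correlation). The phosphatase gene DUSP1 rose from 21.2 ± 2.18 to 226 ± 14.1 CPM and the transcription factor gene EGR1 from 6.88 ± 1.37 to 75.9 ± 1.89 CPM. Heat shock protein genes rose in 13 of 16 and fell in 2 (13 up and 2 down adjusted over the list alone), and without NTC replicate 3 the camera adjusted p was 0.0604. In cPCE_del the heat shock list had a median of 0.60 (camera adjusted p = 0.0430, and adjusted p = 0.572 with an estimated correlation). Oxidative phosphorylation genes rose in 21 of 35 and fell in 0 (21 up and 0 down adjusted over the list alone). In cPCE_del the oxidative phosphorylation list had a median of 0.57 (camera adjusted p = 0.0291, and adjusted p = 0.767 with an estimated correlation).

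DNA replication and S phase genes fell in 20 of 28 and rose in 0 (0 up and 20 down adjusted over the list alone). In cPCE_del the DNA replication list had a median of -0.57 (camera adjusted p = 0.004998, and adjusted p = 0.612 with an estimated correlation). The replicative helicase subunit MCM2 fell from 304 ± 11.5 to 147 ± 9.48 CPM and SLBP, which binds histone mRNAs, from 446 ± 12.3 to 144 ± 9.41 CPM. Replication-dependent histone genes, whose mRNAs mostly lack a poly(A) tail, rose in 10 of 16 and fell in 0 (11 up and 0 down adjusted over the list alone), with H2AC6 from 0.634 ± 0.129 to 6.33 ± 0.223 CPM. In cPCE_del the histone list had a median of 1.44 (camera adjusted p = 0.00543, and adjusted p = 0.0698 with an estimated correlation). Hypoxia and glycolysis genes fell in 16 of 33 and rose in 3 (3 up and 16 down adjusted over the list alone). In cPCE_del the hypoxia and glycolysis list had a median of -0.46 (camera adjusted p = 0.0206, and adjusted p = 0.739 with an estimated correlation). Hexokinase 2 (HK2) fell from 159 ± 25.4 to 24.2 ± 2.67 CPM and the glucose transporter gene SLC2A1 from 64.7 ± 9.18 to 20.5 ± 0.603 CPM. The cell cycle inhibitor CDKN1A rose from 64.4 ± 10.9 to 547 ± 50.4 CPM and MYC fell from 353 ± 35.4 to 175 ± 15.7 CPM. The p53 target list had 8 genes up and 8 down of 25 (camera adjusted p = 0.637). The cPCE_del libraries also differed in reads of low alignment quality, 1.37% to 4.73% of counted reads against 0.378% to 0.484% in NTC, and in depth, which was lower than in every NTC library. Mitochondrially encoded mRNAs took 6.89% to 7.50% of counts against 4.73% to 5.78% in NTC.

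The comparison of rPCE_del with NTC asks the same of the rPCE deletion. Keratin 19 (KRT19), a cytoskeletal protein of luminal epithelium, fell from 528 ± 98.5 to 2.10 ± 0.764 CPM (log2 fold change -7.97 ± 0.23, adjusted p = 3.30e-11). SNAI2, a transcription factor of the epithelial-mesenchymal transition, went from 69.5 ± 9.87 CPM to 0 counts (at least 1000.4-fold lower). EPHA4 rose from 0.144 ± 0.129 to 926 ± 289.9 CPM (adjusted p = 8.71e-11), and HMGCS1, an early enzyme of cholesterol synthesis, rose from 63.1 ± 10.5 to 629 ± 112 CPM (adjusted p = 1.44e-09). Genes of cholesterol synthesis and replication-dependent histones rose and androgen response genes fell, and these 3 lists passed with an estimated correlation too. The histone list stands for RNA quality or capture, and whether its rise is technical was not tested. Of 18109 genes, 4867 were higher and 4965 lower, of which 2099 and 2543 differed at least 2-fold, and camera called 9 of 31 lists.

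Among the 10 largest rises in rPCE_del, the adenylate cyclase gene ADCY8 had 0 counts in NTC and 24.4 ± 1.07 CPM in rPCE_del (at least 779-fold higher), and the hyaluronan synthase gene HAS2 17.2 ± 4.13 CPM against 0 (at least 550.0-fold higher). The GDNF receptor gene GFRA1 rose from 0.008996 ± 0.0156 to 55.7 ± 12.8 CPM with 1 count in NTC (ratio 5321, counting interval 954 to 210249.6). GUCY1B1, a subunit of soluble guanylate cyclase, rose from 0.0424 ± 0.0192 to 78.3 ± 14.4 CPM (adjusted p = 1.11e-11). Among the 10 largest falls was the GABA receptor subunit gene GABBR1, from 11.01 ± 1.57 CPM to 0 counts (at least 158-fold lower). There were 26 genes at 5 CPM or more in NTC with at most 3 counts over rPCE_del, and 30 the other way round. In siNTControl, 22 of the 26 and 17 of the 30 were at 1 CPM or more.

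Cholesterol synthesis genes rose in 22 of 24 and fell in 1 (22 up and 1 down adjusted over the list alone). In rPCE_del the cholesterol synthesis list had a median of 1.95 (camera adjusted p = 3.54e-19, and adjusted p = 0.0264 with an estimated correlation). Squalene synthase (FDFT1) rose from 170.1 ± 13.1 to 1303 ± 250.4 CPM and DHCR7, which makes cholesterol in the final step, from 70.6 ± 6.60 to 301 ± 5.98 CPM. Fatty acid synthesis genes rose in 11 of 17 and fell in 2 (11 up and 2 down adjusted over the list alone), with FADS2 from 44.7 ± 0.930 to 177 ± 16.7 CPM. In rPCE_del the fatty acid synthesis list had a median of 0.74 (camera adjusted p = 8.66e-04, and adjusted p = 0.143 with an estimated correlation). Endoplasmic reticulum chaperone genes rose in 17 of 22 and fell in 0 (17 up and 0 down adjusted over the list alone), with HSPA5, the chaperone BiP, from 916 ± 56.3 to 2415 ± 347 CPM. In rPCE_del the endoplasmic reticulum chaperone list had a median of 0.61 (camera adjusted p = 8.66e-04, and adjusted p = 0.582 with an estimated correlation). Heat shock protein genes rose in 8 of 16 and fell in 2 (9 up and 2 down adjusted over the list alone). In rPCE_del the heat shock list had a median of 0.47 (camera adjusted p = 0.0269, and adjusted p = 0.582 with an estimated correlation). Replication-dependent histone genes rose in 15 of 16 and fell in 0 (16 up and 0 down adjusted over the list alone), with the linker histone H1-2 from 2.03 ± 0.127 to 19.6 ± 7.92 CPM. In rPCE_del the histone list had a median of 2.10 (camera adjusted p = 2.60e-04, and adjusted p = 0.0264 with an estimated correlation).

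Androgen response genes fell in 20 of 38 and rose in 10 (10 up and 20 down adjusted over the list alone). In rPCE_del the androgen response list had a median of -0.50 (camera adjusted p = 1.92e-04, and adjusted p = 0.0264 with an estimated correlation). PMEPA1, an androgen-induced and TGF-beta-induced gene, fell from 689 ± 29.8 to 38.4 ± 5.09 CPM, TMPRSS2 from 36.00 ± 2.69 to 4.49 ± 0.308 CPM and HPGD from 206 ± 11.6 to 24.6 ± 2.84 CPM. Steroid metabolism genes fell in 9 of 15 and rose in 3 (4 up and 9 down adjusted over the list alone), with UGT2B15 from 166 ± 4.08 to 4.74 ± 0.633 CPM, and with the replicate number as a block the adjusted p was 0.0566. In rPCE_del the steroid metabolism list had a median of -0.61 (camera adjusted p = 0.00518, and adjusted p = 0.0658 with an estimated correlation). Hypoxia and glycolysis genes fell in 21 of 33 and rose in 5 (5 up and 21 down adjusted over the list alone). In rPCE_del the hypoxia and glycolysis list had a median of -0.62 (camera adjusted p = 0.00168, and adjusted p = 0.590 with an estimated correlation). The mitophagy receptor gene BNIP3 fell from 180.3 ± 49.9 to 30.7 ± 5.36 CPM and the phosphofructokinase gene PFKP from 41.5 ± 5.93 to 5.02 ± 0.380 CPM. HOXB13, a homeobox transcription factor of prostate, fell from 605 ± 32.6 to 242 ± 35.1 CPM. SLC7A5, a subunit of an amino acid transporter, fell from 2480.4 ± 81.1 to 187 ± 8.28 CPM (adjusted p = 1.11e-11), with its partner SLC3A2 from 792 ± 24.6 to 200.3 ± 50.5 CPM.

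The neuroendocrine, mesenchymal transition (adjusted p = 0.148) and basal lists were not called in rPCE_del, and the genes named here are the members with the smallest p-values or largest changes. Vimentin (VIM), an intermediate filament of mesenchymal cells, rose from 2.98 ± 0.203 to 34.3 ± 6.19 CPM, and N-cadherin (CDH2) rose from 0.0196 ± 0.0172 to 16.3 ± 4.49 CPM with 2 counts in NTC (ratio 779, counting interval 215 to 6443). CDH2 was at 11.5 CPM in siNTControl, so for this gene NTC lay apart from the other 22Rv1 control. The neuroendocrine granule protein chromogranin A (CHGA) rose from 2.84 ± 0.469 to 49.1 ± 19.9 CPM and the neural transcription factor POU3F2 from 0.611 ± 0.250 to 10.3 ± 2.06 CPM. The neuroendocrine list as a whole had 4 up and 5 down of 13 (camera adjusted p = 0.849). Fibroblast markers rose in 3 of 7, COL5A1, LUM and DCN, and fell in 2 (3 up and 2 down adjusted over the list alone). In rPCE_del the fibroblast marker list had a median of 0.47 (camera adjusted p = 0.0282, and adjusted p = 0.143 with an estimated correlation). The camera adjusted p was 0.0968 with the replicate number as a block and 0.0853 with the length trend removed. Without 1 library it ran up to 0.268 (without rPCE_del replicate 1), and was 0.105 without NTC replicate 1, 0.0575 without rPCE_del replicate 2 and 0.0805 without rPCE_del replicate 3. Basal epithelial markers rose in 5 of 9 and fell in 1 (median log2 fold change 1.75, camera adjusted p = 0.284), with SFN, a cell cycle regulator of stratified epithelium, from 124 ± 6.88 to 514 ± 227 CPM. The transcription factors SOX9, from 6.10 ± 0.597 to 89.5 ± 6.53 CPM, and LEF1, from 4.72 ± 0.616 to 52.2 ± 1.40 CPM, rose. The WNT target list had 8 up and 8 down of 20 (camera adjusted p = 0.148), whose median was -0.16 and mean -0.20 although the camera test pointed up. The integrated stress response list differed likewise, with a median of 0.42 and a mean of 0.06 and a camera test that pointed down (adjusted p = 0.998). The oncogene ETV1 rose from 2.32 ± 0.0480 to 63.6 ± 18.3 CPM. In these libraries 2.08% to 3.09% of counted reads had low alignment quality, and rPCE_del replicate 1 stood apart from its group, with 3.15% of reads on no feature, the lowest of the deletion experiment. Mitochondrially encoded mRNAs took 5.75% to 7.20% of counts against 4.73% to 5.78% in NTC, and depth was lower than in every NTC library.

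The comparison of resPCE_del with NTC asks the same of the deletion labelled resPCE. KRT19 fell from 528 ± 98.5 to 1.91 ± 0.0725 CPM (log2 fold change -8.11 ± 0.22, adjusted p = 4.85e-11) and FOLH1 fell from 221 ± 2.46 to 39.4 ± 1.48 CPM (adjusted p = 3.56e-10). PLK3, a stress-response kinase, rose from 7.22 ± 0.225 to 129 ± 1.77 CPM (log2 fold change 4.15 ± 0.13, adjusted p = 1.61e-10). Tenascin C (TNC), a matrix protein, rose from 36.1 ± 2.99 to 348 ± 7.41 CPM (adjusted p = 2.70e-08). Cholesterol synthesis genes rose and prostate luminal markers and hypoxia and glycolysis genes fell. Camera called 7 of 31 lists, none of which passed with an estimated correlation. Of 18109 genes, 3846 were higher and 4358 lower, of which 1457 and 1670 differed at least 2-fold.

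Prostate luminal markers fell in 11 of 18 and rose in 3 (4 up and 11 down adjusted over the list alone). In resPCE_del the luminal marker list had a median of -0.40 (camera adjusted p = 0.00192, and adjusted p = 0.105 with an estimated correlation). Prostatic acid phosphatase (ACP3) fell from 15.04 ± 1.02 to 3.65 ± 0.285 CPM, while the adhesion molecule EPCAM rose from 51.9 ± 1.73 to 109 ± 4.04 CPM. Hypoxia and glycolysis genes fell in 23 of 33 and rose in 5 (5 up and 26 down adjusted over the list alone). In resPCE_del the hypoxia and glycolysis list had a median of -0.79 (camera adjusted p = 0.00192, and adjusted p = 0.714 with an estimated correlation). The oxygen sensor EGLN3 fell from 13.8 ± 3.39 to 1.23 ± 0.128 CPM and hexokinase 1 (HK1) from 168 ± 5.80 to 82.7 ± 2.27 CPM. ERO1A, an oxidase of the endoplasmic reticulum, rose from 34.7 ± 1.28 to 72.3 ± 1.56 CPM. Cholesterol synthesis genes rose in 16 of 24 and fell in 1 (20 up and 1 down adjusted over the list alone), with MSMO1 from 19.7 ± 5.88 to 105 ± 1.61 CPM and mevalonate kinase (MVK) from 19.1 ± 1.40 to 75.4 ± 3.78 CPM. In resPCE_del the cholesterol synthesis list had a median of 0.66 (camera adjusted p = 6.91e-06, and adjusted p = 0.257 with an estimated correlation). Mitochondrially encoded mRNAs rose in 11 of 13 and fell in 0 (11 up and 0 down adjusted over the list alone). In resPCE_del the mitochondrially encoded list had a median of 0.58 (camera adjusted p = 0.0170, and adjusted p = 0.714 with an estimated correlation). With the length trend removed the camera adjusted p was 0.0635. These mRNAs took 6.97% to 7.61% of counts against 4.73% to 5.78% in NTC. Reads of low alignment quality were 1.18% to 1.43% here against 0.378% to 0.484% in NTC.

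The p53 target list had 12 genes up and 4 down of 25 (13 up and 4 down adjusted over the list alone). In resPCE_del the p53 target list had a median of 0.50 (camera adjusted p = 0.0342, and adjusted p = 0.1997 with an estimated correlation). Its camera adjusted p was 0.05004 without NTC replicate 1. The cell cycle regulator CCNG1 rose from 73.6 ± 10.6 to 152 ± 2.004 CPM and the death receptor FAS from 5.22 ± 0.240 to 12.7 ± 0.650 CPM. TGF-beta targets fell in 8 of 18 and rose in 2 (2 up and 8 down adjusted over the list alone), with the transcriptional inhibitor ID2 from 78.5 ± 5.25 to 30.1 ± 1.22 CPM. In resPCE_del the TGF-beta target list had a median of -0.49 (camera adjusted p = 0.0452, and adjusted p = 0.703 with an estimated correlation). The TGF-beta call was lost without NTC replicate 3 (adjusted p = 0.0634) or resPCE_del replicates 1, 2 or 3 (adjusted p = 0.0666, 0.0507 and 0.0507). It was also lost with the size factors of DESeq2 (adjusted p = 0.0545) and with the length trend removed (adjusted p = 0.0641). Androgen response genes fell in 16 of 38 and rose in 14 (16 up and 17 down adjusted over the list alone), with a mean of -0.38 against a median of opposite sign. In resPCE_del the androgen response list had a median of 0.01 (camera adjusted p = 0.0452, and adjusted p = 0.1997 with an estimated correlation). That call was lost without resPCE_del replicates 1, 2 or 3 (adjusted p = 0.108, 0.0883 and 0.0910) and with a block on the replicate number (adjusted p = 0.560). With the size factors of DESeq2 the androgen adjusted p was 0.0568, and with the length trend removed 0.0641. The lipid phosphatase PLPP1 fell from 305 ± 3.42 to 29.2 ± 1.22 CPM (adjusted p = 9.73e-11). Among the 10 largest falls, the transcription factor genes ATOH1 and GLI3 fell from 14.1 ± 0.684 to 0.0511 ± 0.0211 CPM and from 10.1 ± 1.48 to 0.0689 ± 0.00984 CPM. Among the 10 largest rises were CDH2, from 0.0196 ± 0.0172 to 5.46 ± 0.677 CPM with 2 counts in NTC (ratio 262, counting interval 72.1 to 2165), a level under the 11.5 CPM of siNTControl. The semaphorin SEMA3D rose from 0.0409 ± 0.0494 to 19.4 ± 1.81 CPM (adjusted p = 7.95e-10). LGR5, a WNT pathway receptor, rose from 7.71 ± 0.696 to 63.3 ± 1.60 CPM, but was 85.96 CPM in siNTControl, so NTC lay apart. EGR1 rose from 6.88 ± 1.37 to 49.00 ± 1.18 CPM. There was 1 gene at 5 CPM or more in NTC with at most 3 counts over resPCE_del, and 6 the other way round. In siNTControl 2 of these 6 were at 1 CPM or more.

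**Figure D3:**
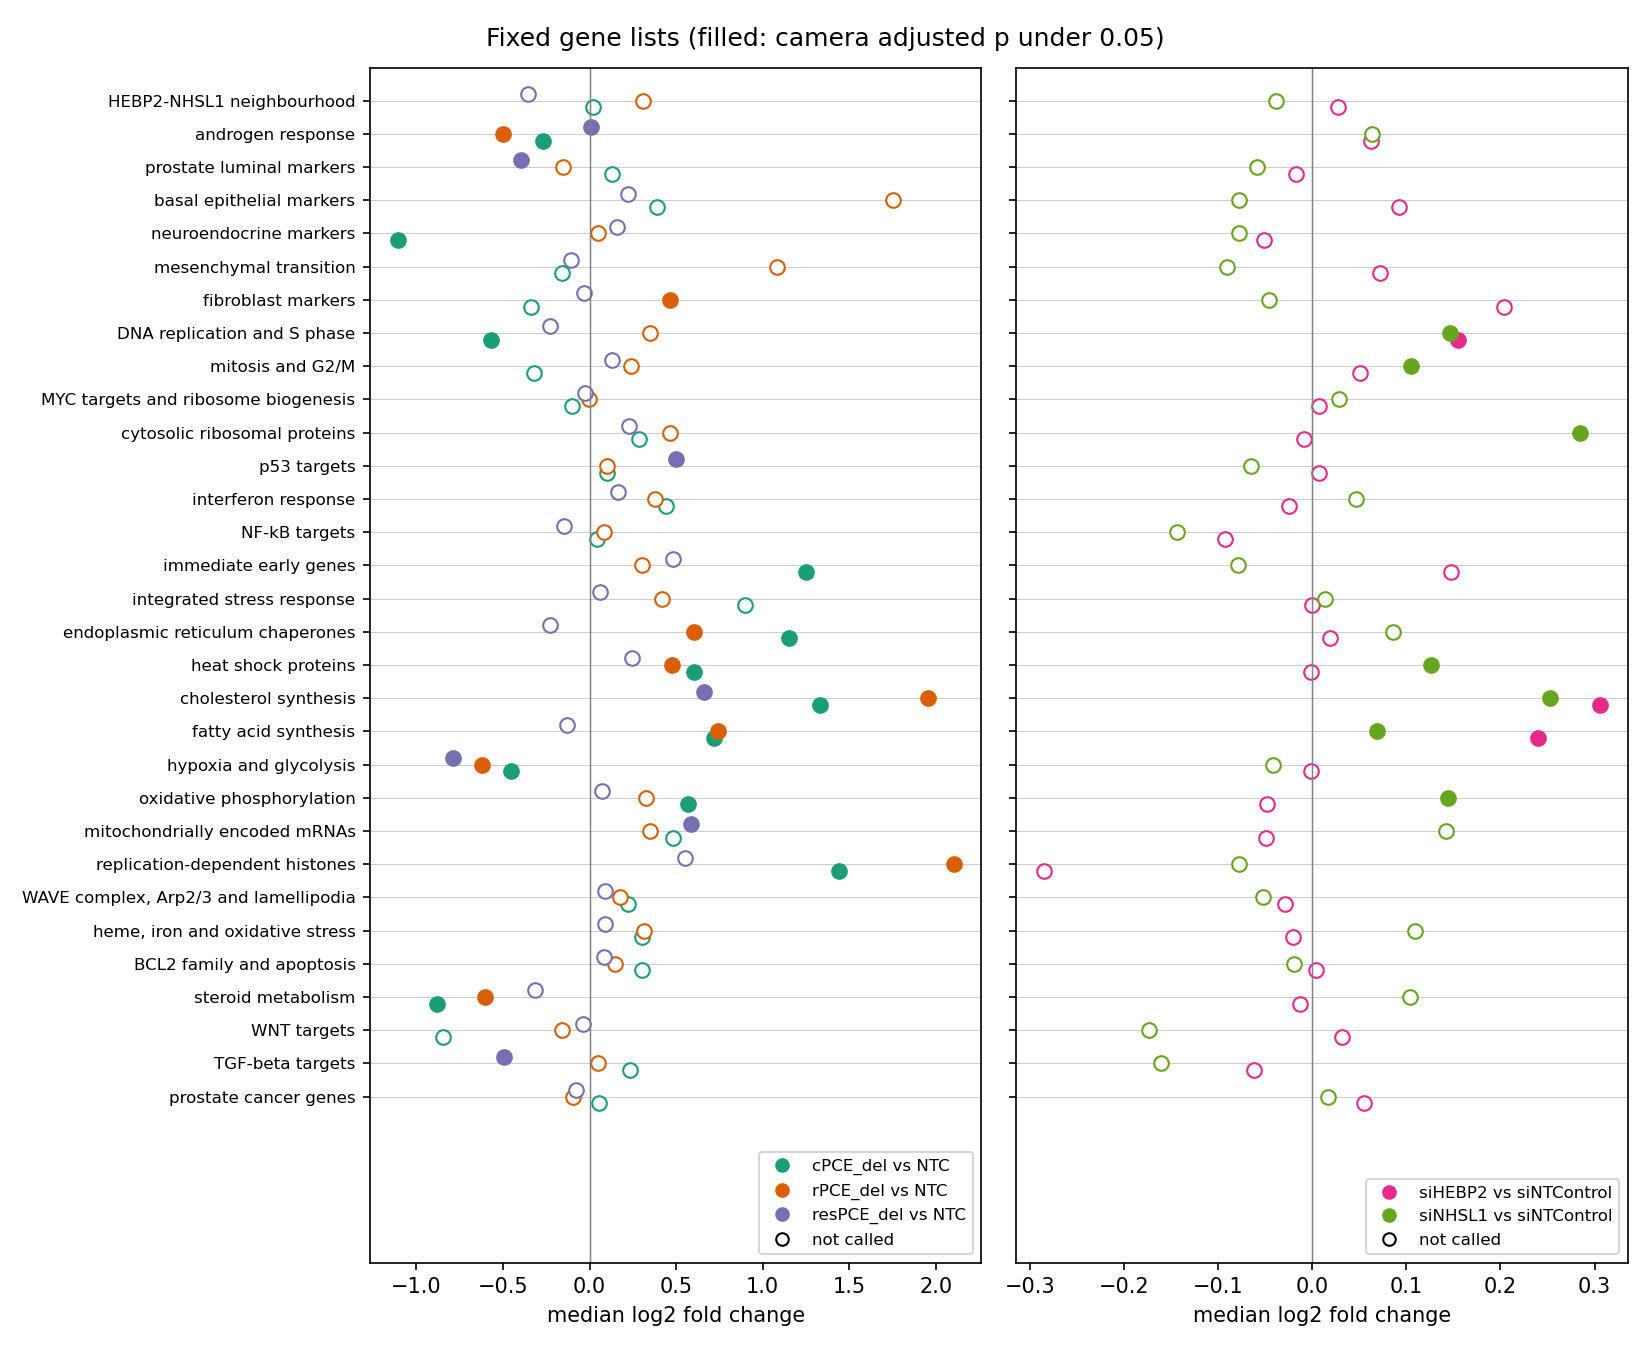
Median log2 fold change of each gene list (symbols) in the comparisons of each group with its control, on a linear axis, with filled symbols for lists called by camera at an adjusted p under 0.05. Cholesterol synthesis was called upward in all 5 comparisons, with medians of 1.33, 1.95 and 0.66 in the deletions and 0.31 and 0.25 with the siRNAs. In cPCE_del (adjusted p = 0.121) and resPCE_del (adjusted p = 0.257) it did not pass with an estimated correlation, and in rPCE_del (adjusted p = 0.0264), siHEBP2 (adjusted p = 0.00209) and siNHSL1 (adjusted p = 0.00802) it did. The deletions and the siRNAs have different controls, and HMGCS1 of this list was lower in NTC than in siNTControl, as given with rPCE_del.

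Some lists were called in no comparison of a deletion group with NTC. The HEBP2-NHSL1 neighbourhood list had 3 genes up and 3 down of 13 in cPCE_del, 7 and 3 in rPCE_del and 2 and 4 in resPCE_del (camera adjusted p = 0.851, 0.299 and 0.121). In it CITED2, a transcriptional co-regulator, fell from 181 ± 12.2 to 78.01 ± 3.77 CPM in cPCE_del. REPS1, an endocytosis adaptor, fell from 73.4 ± 3.58 to 37.02 ± 0.764 CPM in resPCE_del, where 92.8% of the genes beyond NHSL1 had a log2 fold change below 0. Interferon response genes rose in 15, 16 and 11 of 34 and fell in 4, 9 and 9 in the same order (camera adjusted p = 0.148, 0.224 and 0.630). Cytosolic ribosomal protein genes rose in 12, 16 and 4 of 35 and fell in 0 (camera adjusted p = 0.237, 0.169 and 0.442). Mitosis genes rose in 1, 11 and 8 of 28 and fell in 15, 2 and 5 (camera adjusted p = 0.0662, 0.299 and 0.612). Mesenchymal transition genes rose in 5, 10 and 5 of 15 and fell in 7, 4 and 7 (camera adjusted p = 0.464, 0.148 and 0.612). MYC targets rose in 4, 7 and 6 of 30 and fell in 7, 7 and 3 (camera adjusted p = 0.846, 0.998 and 0.746). NF-kB targets rose in 6, 5 and 3 and fell in 6, 5 and 4 of 15 (camera adjusted p = 0.184, 0.802 and 0.612). The list of the WAVE complex, to which NHSL1 binds, rose in 10, 7 and 9 of 29 and fell in 6, 7 and 6 (camera adjusted p = 0.550, 0.710 and 0.612). Its member CYFIP2 rose from 4.17 ± 0.423 to 51.99 ± 3.04 CPM in cPCE_del. Heme and iron genes rose in 12, 15 and 5 of 29 and fell in 5, 5 and 6 (camera adjusted p = 0.362, 0.261 and 0.725). Apoptosis genes rose in 15, 9 and 10 and fell in 6, 6 and 6 of 29 (camera adjusted p = 0.525, 0.606 and 0.612). Prostate cancer genes rose in 10, 10 and 9 of 30 and fell in 10, 11 and 10 (camera adjusted p = 0.803, 0.718 and 0.591). Median and mean differed in sign for the neighbourhood list in cPCE_del (0.02 and -0.23), prostate cancer genes in cPCE_del (0.06 and -0.37), fibroblast markers in cPCE_del (-0.34 and 0.14), basal epithelial markers in resPCE_del (0.22 and -0.32) and mesenchymal transition genes in resPCE_del (-0.11 and 0.39). Endothelial and immune cell markers had 1 and 2 measured genes and were not tested.

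The deletion groups were also compared with each other, which avoids the shared NTC libraries. Against rPCE_del, cPCE_del had 4533 genes higher and 4871 lower. Neuroendocrine markers were lower in cPCE_del in 8 of 13 and higher in 3 (3 up and 8 down adjusted over the list alone). In cPCE_del against rPCE_del the neuroendocrine marker list had a median of -1.75 (camera adjusted p = 7.88e-05, and adjusted p = 0.0405 with an estimated correlation). DNA replication genes were lower in 25 of 28 and higher in 1 (1 up and 26 down adjusted over the list alone), and mitosis genes lower in 23 of 28 and higher in 0 (0 up and 23 down adjusted over the list alone). In cPCE_del against rPCE_del the DNA replication list had a median of -0.92 (camera adjusted p = 2.31e-05) and the mitosis list -0.67 (camera adjusted p = 0.00241). With an estimated correlation the adjusted p was 0.394 for both. Cholesterol synthesis genes were lower in 15 of 24 and higher in 4 (4 up and 16 down adjusted over the list alone). In cPCE_del against rPCE_del the cholesterol synthesis list had a median of -0.81 (camera adjusted p = 0.00241, and adjusted p = 0.431 with an estimated correlation). Immediate early genes were higher in 11 of 16 and lower in 3 (11 up and 3 down adjusted over the list alone), and endoplasmic reticulum chaperones higher in 15 of 22 and lower in 1 (16 up and 2 down adjusted over the list alone). In cPCE_del against rPCE_del the immediate early list had a median of 0.63 (camera adjusted p = 0.00291, and adjusted p = 0.394 with an estimated correlation). In cPCE_del against rPCE_del the endoplasmic reticulum chaperone list had a median of 0.59 (camera adjusted p = 0.0195, and adjusted p = 0.534 with an estimated correlation). PRUNE2 had 0 counts in cPCE_del and 534 ± 256 CPM in rPCE_del (at least 7289.6-fold lower).

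Against resPCE_del, cPCE_del had 4776 genes higher and 5191 lower, and camera called 14 lists, none of which passed with an estimated correlation. Of these 14 lists 4 were lower in cPCE_del. Neuroendocrine markers were lower in 8 of 13 and higher in 1 (1 up and 8 down adjusted over the list alone). In cPCE_del against resPCE_del the neuroendocrine marker list had a median of -0.59 (camera adjusted p = 1.79e-04, and adjusted p = 0.0585 with an estimated correlation). Mitosis genes were lower in 21 of 28 and higher in 0 (1 up and 22 down adjusted over the list alone). In cPCE_del against resPCE_del the mitosis list had a median of -0.47 (camera adjusted p = 0.0168, and adjusted p = 0.436 with an estimated correlation). Steroid metabolism genes were lower in 6 of 15 and higher in 4 (4 up and 6 down adjusted over the list alone), and with the replicate number as a block the adjusted p was 0.0597. In cPCE_del against resPCE_del the steroid metabolism list had a median of -0.41 (camera adjusted p = 0.00657, and adjusted p = 0.149 with an estimated correlation). DNA replication genes were lower in 15 of 28 and higher in 0 (0 up and 15 down adjusted over the list alone). In cPCE_del against resPCE_del the DNA replication list had a median of -0.34 (camera adjusted p = 0.0453, and adjusted p = 0.716 with an estimated correlation). The DNA replication call was lost with the size factors of DESeq2 (adjusted p = 0.0511) and without cPCE_del replicate 2 (adjusted p = 0.0734), resPCE_del replicate 1 (adjusted p = 0.0501) or resPCE_del replicate 2 (adjusted p = 0.0536). Endoplasmic reticulum chaperones were higher in 21 of 22 and lower in 0 (21 up and 0 down adjusted over the list alone), and fatty acid synthesis genes higher in 11 of 17 and lower in 4 (11 up and 4 down adjusted over the list alone). In cPCE_del against resPCE_del the endoplasmic reticulum chaperone list had a median of 1.24 (camera adjusted p = 1.84e-09) and fatty acid synthesis 0.43 (camera adjusted p = 3.48e-04). With an estimated correlation the adjusted p was 0.149 for both. SYT4, a synaptotagmin of vesicle release, was 0.113 ± 0.0824 against 1647 ± 45.6 CPM (log2 fold change -13.96 ± 0.21, adjusted p = 9.50e-14), and STRA6, the retinol transporter gene, 93.3 ± 6.36 CPM against 0 counts (at least 3129-fold higher). Against resPCE_del, rPCE_del had 4624 genes higher and 4654 lower, with 10 lists called and none with an estimated correlation. Cholesterol synthesis genes were higher in 19 of 24 and lower in 1 (19 up and 1 down adjusted over the list alone), and p53 targets lower in 12 of 25 and higher in 4 (4 up and 12 down adjusted over the list alone). In rPCE_del against resPCE_del the cholesterol synthesis list had a median of 1.15 (camera adjusted p = 5.05e-08, and adjusted p = 0.117 with an estimated correlation). In rPCE_del against resPCE_del the p53 target list had a median of -0.62 (camera adjusted p = 0.0124, and adjusted p = 0.0803 with an estimated correlation). The neighbourhood list was higher in 8 of 13 and lower in 2 (8 up and 2 down adjusted over the list alone), with REPS1 93.6 ± 4.15 against 37.02 ± 0.764 CPM. In rPCE_del against resPCE_del the neighbourhood list had a median of 0.65 (camera adjusted p = 0.00826, and adjusted p = 0.0803 with an estimated correlation). The protocadherin gene PCDH10 was at 154 ± 20.7 CPM in rPCE_del against 0 counts in resPCE_del (at least 5166-fold higher). The cPCE_del libraries held at most 18917342 counts against at least 30595625 in resPCE_del.

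The fold changes of the deletion groups against NTC were correlated across 18109 genes, which are not independent replicates: Pearson r was 0.434 for cPCE_del and rPCE_del, 0.334 for cPCE_del and resPCE_del and 0.502 for rPCE_del and resPCE_del (Spearman 0.445, 0.353 and 0.458). All 3 use the same NTC libraries, and sets simulated with no change gave r = 0.399, 0.443 and 0.454 from the shared controls alone, but covariances of only 0.0227, 0.0225 and 0.0227 against 1.24, 0.645 and 0.880. In all 3 comparisons 1127 genes were higher and 1770 lower, where independence gives 275 and 357 and the simulated sets gave 0. The 3 controls cannot be divided between comparisons, so how much of this excess comes from the NTC libraries is not settled by these counts. Among the shared changes were lower HPGD, SLC7A5 and UGT2B15 and higher MSMO1, HSD17B7 and CYFIP2.

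**Figure D4:**
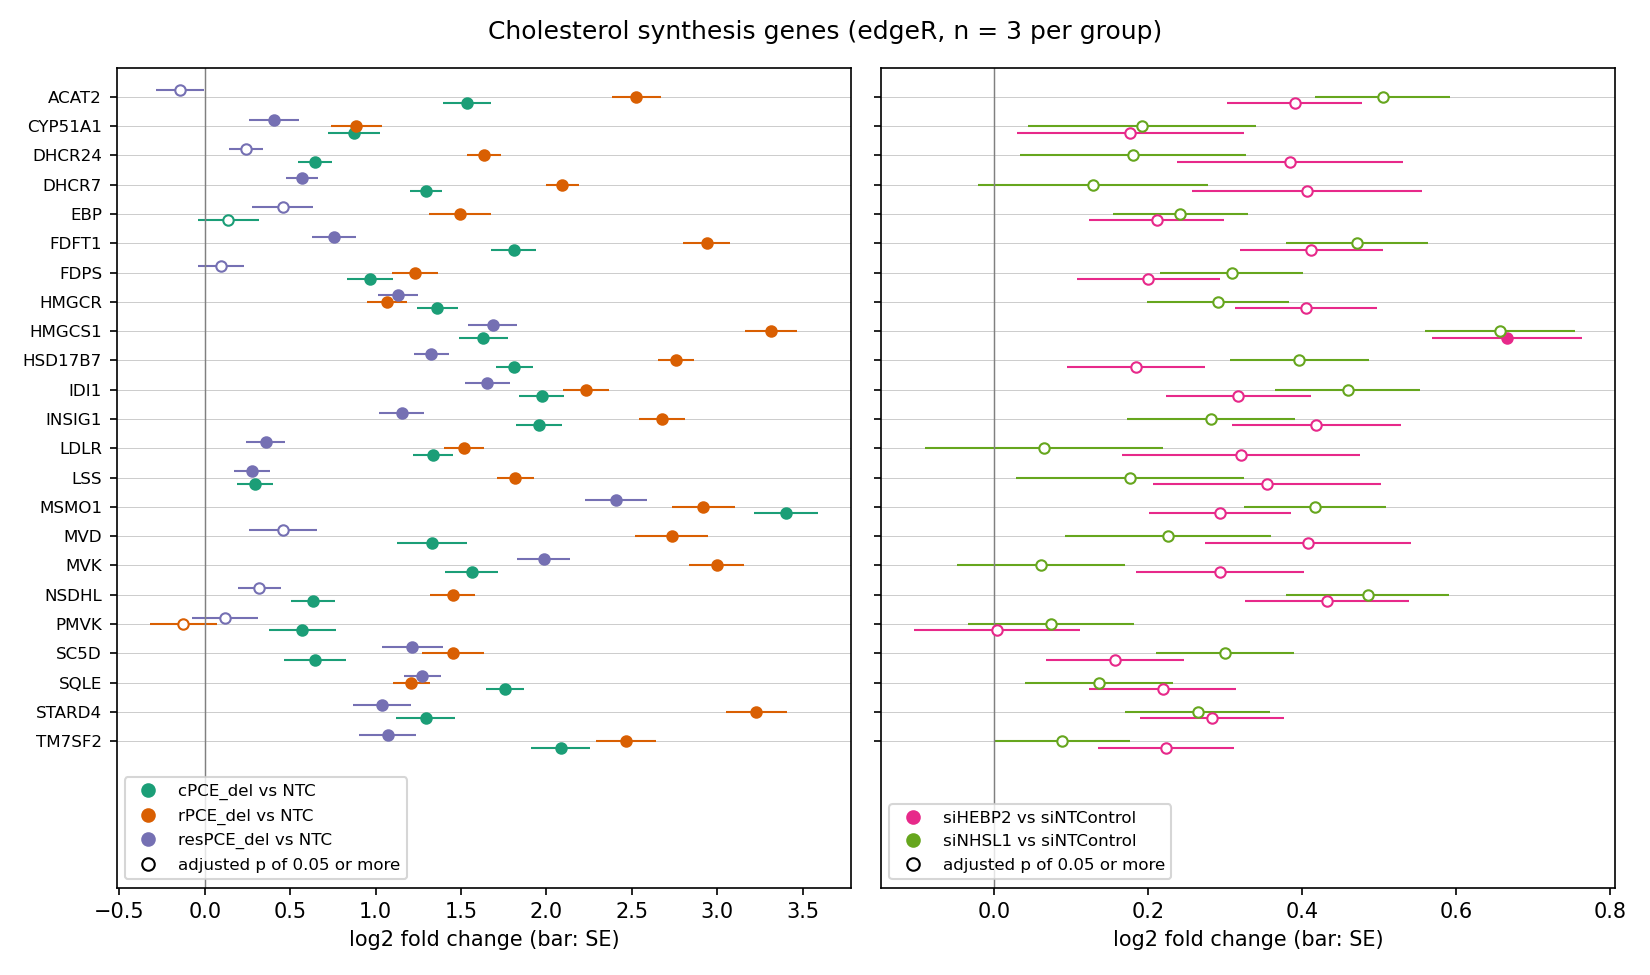
Log2 fold change against the control for 23 of the 24 measured genes of the cholesterol synthesis list (points) in the 5 comparisons with a control, on a linear axis, with bars for the SE and open symbols at an adjusted p of 0.05 or more. In the deletion groups 22, 22 and 16 of 24 genes rose, and with the siRNAs HMGCS1 rose in siHEBP2.

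With siHEBP2 the comparison with siNTControl asks what changes when HEBP2 RNA is reduced by siRNA. HMGCS1 rose from 737 ± 25.7 to 1170.0 ± 60.9 CPM (log2 fold change 0.67 ± 0.097, adjusted p = 0.0435), and this and the fall of HEBP2 were the 2 genes of 17399 that passed in edgeR. The HMGCS1 call was lost in each fit without 1 of the 6 libraries (adjusted p = 0.383, 0.433 and 0.458 without siNTControl replicates 1, 2 and 3, and 0.257, 0.234 and 0.678 without siHEBP2 replicates 1, 2 and 3). HMGCS1 passed without siNHSL1 replicate 3, as given below. At an unadjusted p under 0.05 there were 1141 genes, and DESeq2 called 13 higher and 22 lower. Of 24 cholesterol synthesis genes 1 rose (16 adjusted over the list alone). In siHEBP2 the cholesterol synthesis list had a median of 0.31 (camera adjusted p = 2.35e-24, and adjusted p = 0.00209 with an estimated correlation). Camera also called DNA replication genes, where 0 of 28 passed over all genes (1 adjusted over the list alone). In siHEBP2 the DNA replication list had a median of 0.15 (camera adjusted p = 2.23e-08, and adjusted p = 0.0135 with an estimated correlation). Camera called fatty acid synthesis genes too, where 0 of 17 passed (4 up and 1 down adjusted over the list alone). In siHEBP2 the fatty acid synthesis list had a median of 0.24 (camera adjusted p = 4.70e-05, and adjusted p = 0.0981 with an estimated correlation). On simulated data of this size, 85.1% of 2-fold and 61.2% of 1.5-fold changes were recovered. Those sets changed 200 well-counted genes and held no library that stood apart, so the share recovered in the real libraries may be lower.

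With siNHSL1, 0 genes were higher and 1 lower in edgeR, with 1893 genes at an unadjusted p under 0.05 and 27 higher and 59 lower by DESeq2. The 1 gene was ALPK3, a kinase gene known from heart muscle, which fell from 41.1 ± 1.73 to 23.2 ± 2.72 CPM (log2 fold change -0.82 ± 0.11, adjusted p = 0.0488). That call was lost without siNTControl replicates 1, 2 or 3 (adjusted p = 0.439, 0.323 and 0.299) or siNHSL1 replicate 2 (adjusted p = 0.0797). HMGCS1 was 1163 ± 113 against 737 ± 25.7 CPM (log2 fold change 0.66 ± 0.097, adjusted p = 0.0511, and 5.66e-08 by DESeq2). Of 24 cholesterol synthesis genes 0 passed over all genes (13 adjusted over the list alone), and of 28 DNA replication genes 0 (2 adjusted over the list alone). In siNHSL1 the cholesterol synthesis list had a median of 0.25 (camera adjusted p = 8.29e-15, and adjusted p = 0.00802 with an estimated correlation). In siNHSL1 the DNA replication list had a median of 0.15 (camera adjusted p = 8.97e-06, and adjusted p = 0.0375 with an estimated correlation). Camera also called 5 lists with 0 genes past the test over all genes and, in the order given, 0, 0, 0, 0 and 3 higher adjusted over the list alone. In siNHSL1 the ribosomal protein list had a median of 0.28 (camera adjusted p = 1.93e-10) and oxidative phosphorylation 0.14 (camera adjusted p = 0.00855). The mitosis list had a median of 0.10 (camera adjusted p = 0.0129) and heat shock 0.13 (camera adjusted p = 0.0280). With an estimated correlation the adjusted p of each of these was 0.692. In siNHSL1 the fatty acid synthesis list had a median of 0.07 (camera adjusted p = 0.0374, and adjusted p = 0.533 with an estimated correlation). Without siNHSL1 replicate 3 the heat shock (adjusted p = 0.586) and oxidative phosphorylation (adjusted p = 0.0945) lists pointed down, and the ribosomal (adjusted p = 0.180) and mitosis (adjusted p = 0.135) calls ended. The mitosis call was also lost without siNTControl replicate 3 (adjusted p = 0.110). The heat shock call was lost without siNTControl replicates 1 or 2 (adjusted p = 0.0813 and 0.0564). The fatty acid call was lost without siNTControl replicates 1 or 2 (adjusted p = 0.0813 and 0.0549) or siNHSL1 replicates 1 or 2 (adjusted p = 0.361 and 0.140), but not without siNHSL1 replicate 3. The library siNHSL1 replicate 3 had the lowest share of reads on no feature (8.98%) and the highest mitochondrial share (7.19%) of the siRNA experiment.

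The siRNA fits were repeated without siNHSL1 replicate 3, a choice made after the data were seen. Without it 243 genes were higher and 234 lower with siHEBP2, 5 and 13 of them at least 2-fold, and 79 higher and 85 lower with siNHSL1, 3 and 3 of them at least 2-fold. In these fits HMGCS1 was 1179.6 ± 61.8 CPM with siHEBP2 (n = 3, adjusted p = 1.31e-11) and 1223 ± 101 CPM with siNHSL1 (n = 2, adjusted p = 2.64e-11), against 743 ± 23.1 CPM in siNTControl. Cholesterol synthesis genes rose in 19 and 16 of 24 (camera adjusted p = 1.16e-48 and 1.53e-51, and adjusted p = 0.00546 and 0.00515 with an estimated correlation). DNA replication genes rose in 11 and 5 of 28 (camera adjusted p = 1.92e-13 and 1.19e-13, and adjusted p = 0.0215 and 0.0242 with an estimated correlation). Fatty acid synthesis genes rose in 9 and 6 of 17 and fell in 1 and 0 (camera adjusted p = 1.92e-13 and 1.08e-12, and adjusted p = 0.0215 and 0.0242 with an estimated correlation). With both siRNAs 63 genes were higher and 56 lower, where independence gives 1.07 and 1.11 and 20 sets simulated with no change gave 0.15 and 0.05 on average. Both comparisons share the 3 siNTControl libraries, which cannot be divided, so part of this excess may come from them.

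The siRNA groups compared with each other differed in 2 genes in edgeR, both lower in siHEBP2 (1037 genes at an unadjusted p under 0.05, and 2 higher and 3 lower by DESeq2). The first was HEBP2, 56.4 ± 10.6 against 139.8 ± 18.2 CPM (log2 fold change -1.31 ± 0.13, adjusted p = 8.86e-04). The other was the nucleotide sugar transporter gene SLC35D1, 32.8 ± 1.27 against 53.4 ± 2.49 CPM (log2 fold change -0.70 ± 0.10, adjusted p = 0.0493). Camera called 5 lists, each with 0 genes past the test and 0 adjusted over the list alone. Ribosomal protein genes had a median of -0.29 (camera adjusted p = 8.45e-13, and adjusted p = 0.688 with an estimated correlation). Oxidative phosphorylation genes had a median of -0.22 (camera adjusted p = 7.66e-06, and adjusted p = 0.688 with an estimated correlation), and without siNHSL1 replicate 3 the camera adjusted p was 0.973. Heat shock protein genes had a median of -0.15 (camera adjusted p = 0.0472, and adjusted p = 0.728 with an estimated correlation). Steroid metabolism genes had a median of -0.17 and immediate early genes 0.14 (for each, camera adjusted p = 0.0472, and adjusted p = 0.688 with an estimated correlation). Without siNHSL1 replicate 3 these 3 calls ended (adjusted p = 0.973, 0.368 and 0.129). The heat shock call was also lost without siHEBP2 replicates 1 or 3 (adjusted p = 0.126 and 0.0834) and with the length trend removed (adjusted p = 0.0689). The steroid metabolism call was lost without siHEBP2 replicates 1, 2 or 3 (adjusted p = 0.0831, 0.0754 and 0.0834), siNHSL1 replicate 2 (adjusted p = 0.0828) or with the length trend removed (adjusted p = 0.0687). The immediate early call was lost without siHEBP2 replicates 2 or 3 (adjusted p = 0.219 and 0.108) or siNHSL1 replicate 1 (adjusted p = 0.173). Across genes the fold changes of the siRNAs correlated at r = 0.534, where simulated sets with the same controls gave 0.5004. Of the 10 pairs of comparisons with a control, the 6 pairs of a deletion and an siRNA had different controls, and their r ranged from 0.0330 to 0.129.

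After these comparisons the genes around HEBP2 and NHSL1 were followed along chromosome 6, a step chosen after the values were seen. Only genes with a mean of at least 5 CPM over the groups compared were used. In resPCE_del the 69 such genes beyond NHSL1 had a median log2 fold change of -0.68 against NTC, with 92.8% below 0. The 156 of the long arm up to HEBP2 had a median of 0.13 and the short arm -0.09. Of 9468 other, overlapping runs of 69 neighbouring genes in the genome, 0 had a median as low as -0.68 (lowest -0.65). In cPCE_del the long arm without HEBP2 and NHSL1 had a median of 0.64 over 240 genes, with 79.6% above 0, against -0.02 on the short arm, and 0 of 5775 other runs were as high (highest 0.51). HEBP2 and NHSL1 thus fell in cPCE_del within a stretch whose other genes were mostly higher. In rPCE_del the medians were 0.33 up to HEBP2, 0.18 beyond NHSL1 and 0.18 on the short arm. Other chromosomes shifted too. In cPCE_del, rPCE_del and resPCE_del, in that order, the medians were -0.58, -0.46 and -0.30 for chromosome 13, -0.53, -0.46 and -0.44 for chromosome 15 and -0.07, -0.52 and -0.22 for chromosome 18. All 3 groups share the NTC libraries, so a shift in all 3 may belong to NTC. DNA copy number was not analysed here.

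**Figure D5:**
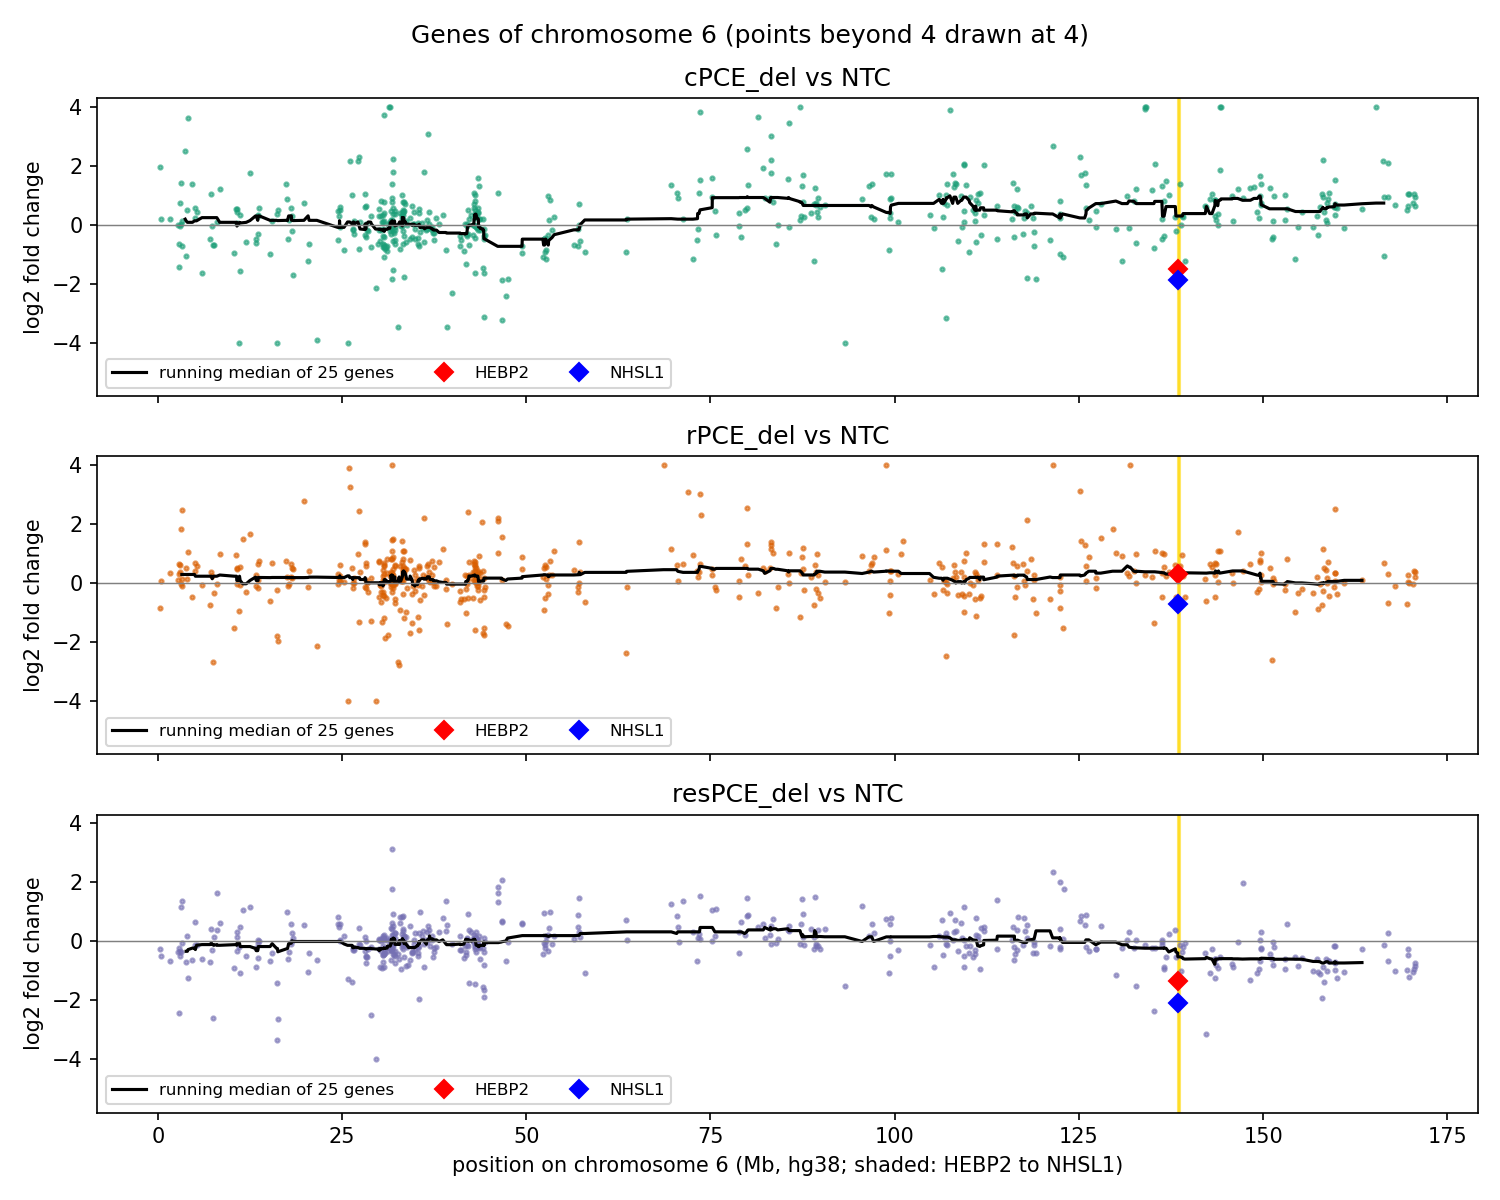
Log2 fold change against NTC of genes with a mean of at least 5 CPM along chromosome 6 (position in megabases of hg38) in each deletion group, with 1 point per gene, a line for the running median and HEBP2 and NHSL1 marked. Genes beyond NHSL1 lay mostly below 0 in resPCE_del (median -0.68), and genes of the long arm mostly above 0 in cPCE_del (median 0.64).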

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

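The tests below of genes at or under the floor, of keratins, of chromosome 6, of each group in turn as the odd one and of read shares in siNHSL1 replicate 3 were chosen after the result was seen, as were the thinned counts and the removal of the length trend as settings.

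Against NTC, HEBP2 rose in rPCE_del and fell in cPCE_del and resPCE_del, and tested directly it was higher in rPCE_del than in both, with log2 fold changes of -1.79 for cPCE_del against rPCE_del and 1.64 for rPCE_del against resPCE_del. Its rise in rPCE_del was no larger than the median of 0.33 of the genes of the long arm up to HEBP2. For REPS1 the difference between rPCE_del and resPCE_del was 1.34. Reads of low alignment quality, outside the gene counts, averaged 3.15% in cPCE_del, 2.43% in rPCE_del and 1.32% in resPCE_del against 0.422% in NTC. Reads aligned to more than 1 place averaged 5.07% in resPCE_del, and reads that did not align averaged 8.56% in siHEBP2, and in each of these cases every library lay above all its controls. Other averages above the control came from groups that overlapped it: 5.24% aligned to more than 1 place in rPCE_del, and 11.9%, 10.8% and 8.56% not aligned in cPCE_del, rPCE_del and siNHSL1.

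Depth does not account for the 10223, 9832 and 8204 genes that differed from NTC in cPCE_del, rPCE_del and resPCE_del, since 8886, 8349 and 6497 genes passed with every library thinned to the smallest total, and neither does a trend on exon length, since 10959, 10752 and 9276 passed with it removed. Regional copy number as the whole source is argued against by bins of 10 Mb, which explained 0.0441, 0.0807 and 0.0732 of the variance. An acute reduction of HEBP2 RNA is argued against by genes called at 2-fold, whose median change with siHEBP2 in the direction of the deletion was 0.0224 for cPCE_del (4318 genes) and 0.0177 for resPCE_del (2635 genes). A minority of other cells among cells like NTC would leave no gene of NTC near 0, yet 61 genes in cPCE_del and 26 in rPCE_del were (1 in resPCE_del, too few to decide), and basal cells are argued against in rPCE_del by KRT5, KRT14 and KRT17 at 0.0223 CPM together, while other lines remain open, with basal marker medians of 0.392, 1.75 and 0.219. What stays open is the deletions themselves, differences between clones, since the labels do not say whether these cells are clones, unrecorded library batches that may follow the groups, and NTC standing apart, on which siNTControl does not decide: it lay nearer to the deletions in 61.2% of the 2872 genes called alike in all 3 and also measured in the siRNA experiment (1759 genes), but with cPCE_del, rPCE_del or resPCE_del as the odd group it lay nearer to the others in 72.7%, 74.2% and 45.2%.

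With 10 splits of the 6 libraries of a comparison, the share of splits as large as the real one cannot go under 0.1. The real split gave 11691, 7371 and 11628 calls for cPCE_del, rPCE_del and resPCE_del against NTC, 6834 for cPCE_del against rPCE_del, 12222 for cPCE_del against resPCE_del and 7290 for rPCE_del against resPCE_del, with 0 as the highest of the other splits and 1 split as large, the real one, in each. In siHEBP2 against siNTControl it gave 420 (highest other 7, 1 split as large), in siHEBP2 against siNHSL1 1 (highest other 0, 1 split as large), and in siNHSL1 against siNTControl 0, as did all 10 splits.

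Along chromosome 6, genes beyond NHSL1 were lower in resPCE_del and genes of the long arm were higher in cPCE_del. In both, 0 percent of other runs of as many neighbouring genes were as extreme. These runs overlap, the stretches were picked after the values were seen, and the lowest other run in resPCE_del was -0.65 against -0.68. A chance run is thus not excluded. A copy-number loss toward the end of the arm in resPCE_del, with 92.8% of these genes below 0, and a gain of the long arm in cPCE_del, with 79.6% above 0, remain candidate explanations that cannot be told apart from a regional change in regulation, because DNA was not analysed here. The best single step in resPCE_del lay between HINT3 and TRMT11, 12.4 Mb from NHSL1, rather than at NHSL1. HEBP2 and NHSL1 thus lay within the lowered stretch.

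The library siNHSL1 replicate 3 stood apart from the other 8 of the siRNA experiment, and no biological explanation other than cells of another type was tested. A wrong label or a failed transfection is argued against by NHSL1 at 7.57 CPM in it, below the 16.5 and 15.6 CPM of siNHSL1 replicates 1 and 2. Whether its lower NHSL1 sets it apart was not tested. RNA quality or read composition is consistent with 4 of 5 read shares outside the range of the other 8 libraries, and may account for it. A loss of long transcripts is left open by a Spearman correlation of -0.195 with exon length across genes, and cells of another type are left open because only 2 of 4 marker lists had at least 5 measured genes (0 of these 2 lay above the other libraries). In rPCE_del replicate 1, where the same correlation was -0.431, such a loss may account for its distance from its group.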

How the results depend on the processing

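The settings here called added were chosen after seeing the data: library size alone, thinned counts, the length trend and the fits with siNHSL1 replicate 3 or rPCE_del replicate 1 left out of the shared spread. Of the alternatives for gene counts, 84 of the 108 fits without 1 library, 13 of 18 values by DESeq2, 17 of 18 with its size factors and 16 of 18 with a replicate block stayed within 1.5 times the reported count. All moved counts but 1 were in the siRNA experiment. Of named genes, 667 kept their direction and side of the threshold by DESeq2, 15 became calls and 1 lost its call; over the fits without 1 library these numbers were 4176, 15 and 45. Except where the construction shows it, the cause was not tested.

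With an estimated correlation the lists called were 0 in cPCE_del, 3 in rPCE_del and 0 in resPCE_del against NTC, 1 in cPCE_del against rPCE_del, 0 in cPCE_del against resPCE_del, 0 in rPCE_del against resPCE_del, 2 in siNHSL1 against siNTControl and 0 in siHEBP2 against siNHSL1, where the correlation between genes of a list is the choice that differs. With the length trend removed (added) they were 4 in resPCE_del against NTC, 9 in cPCE_del against resPCE_del, 5 in siHEBP2 against siNTControl and 3 in siHEBP2 against siNHSL1. In fits without 1 library the lists called ranged from 6 to 10 in cPCE_del against rPCE_del (10 without rPCE_del replicate 1), 9 to 14 in cPCE_del against resPCE_del (9 without resPCE_del replicate 1), 4 to 9 in siNHSL1 against siNTControl and 2 to 6 in siHEBP2 against siNHSL1. In a fit of only 6 libraries 5820 genes were higher in resPCE_del than in NTC.

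With siHEBP2 against siNTControl, genes higher and lower were 13 and 22 by DESeq2, 16 and 26 with no filter on low counts, 205 and 215 in a fit of 6 libraries, 0 and 2 in a fit of all 21, and 243 and 234 with siNHSL1 replicate 3 left out of the shared spread (added), which also called 5 lists. Genes higher were 0 with at least 50 counts in 3 libraries and 0 with library size alone (added). Without 1 library they were 0 to 0 higher and 0 to 1 lower, and the log2 fold change of HEBP2 ranged from -1.31 to -1.05, with calls lost at -1.12 without siNTControl replicate 1, -1.18 without siNTControl replicate 3 and -1.20 without siHEBP2 replicate 2.

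With siNHSL1 against siNTControl, genes higher and lower were 27 and 59 by DESeq2, 40 and 101 with no filter, and 1 and 2 with the length trend removed (added). Genes higher were 1 with DESeq2 size factors, 1 with a replicate block and 1 with thinned counts (added), and genes lower 0 with at least 50 counts, 0 in a fit of 6 libraries and 0 with library size alone (added). Without 1 library they ranged from 0 to 79 higher and 0 to 85 lower, the highest without siNHSL1 replicate 3. NHSL1 became a call at -1.22 by DESeq2 and -1.20 with the length trend removed (added), and without 1 library ranged from -1.41 to -0.95, as a call without siNHSL1 replicate 1 or 3. Without siNHSL1 replicate 3 the direction of the heat shock list turned to -1, that of oxidative phosphorylation to -1, and that of heat shock in siHEBP2 against siNHSL1 to 1.

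With siHEBP2 against siNHSL1, genes higher and lower were 4 and 5 with no filter and 1 and 1 in a fit of all 21 libraries. Genes higher were 2 by DESeq2 and 1 with the length trend removed (added), and genes lower 1 with at least 50 counts, 1 with a replicate block, 1 in a fit of 6 libraries and 1 with library size alone (added). Without 1 library they ranged from 0 to 3 higher and 1 to 4 lower.

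Correlations of fold changes with at least 50 counts in 3 libraries were 0.451 for cPCE_del and rPCE_del, 0.327 for cPCE_del and resPCE_del, 0.121 for cPCE_del and siNHSL1, 0.119 for rPCE_del and siHEBP2 and 0.181 for rPCE_del and siNHSL1. Without 1 library they ranged from 0.414 to 0.440 for cPCE_del and rPCE_del, 0.327 to 0.346 for cPCE_del and resPCE_del, 0.444 to 0.625 for siHEBP2 and siNHSL1, 0.0908 to 0.137 for rPCE_del and siNHSL1 and 0.0176 to 0.105 for resPCE_del and siNHSL1, the lowest of the last 2 without siNHSL1 replicate 3.

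Replicate numbers were not taken to pair the libraries, because not every pair with the same number correlated over 0.1. Residuals of libraries with the same number correlated at -0.0197 on average in the deletion experiment (-0.192 to 0.204, 2 of 18 pairs over 0.1) and 0.0508 in the siRNA experiment (-0.0113 to 0.0935, 0 of 9 over 0.1, against -0.0252 for other pairs). Libraries correlated best with their own number in 10 of 36 cases in the deletion experiment and 16 of 18 in the siRNA experiment, a hint of weak pairing in the latter that comes from the data and not the design. The block moved 2 of 18 gene counts, each by 1 gene, and ended the calls of 8 lists and 3 named genes, while 2 named genes became calls. On simulated data 41.8% of 1.5-fold changes were recovered for cPCE_del.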

Other observations

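The fits without siNHSL1 replicate 3, the source of the siRNA genes named here, were chosen after the data were seen.

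Genes outside cholesterol synthesis also moved in the siRNA experiment once siNHSL1 replicate 3 was left out. With siHEBP2 (n = 3) the laminin chain gene LAMA3 rose from 9.86 ± 0.367 to 16.8 ± 1.69 CPM (adjusted p = 2.85e-04) and RALYL, an RNA-binding protein gene, from 7.50 ± 0.750 to 12.3 ± 1.40 CPM (adjusted p = 0.00321). GABBR1, a subunit of the GABA-B receptor, fell with a log2 fold change of -1.10 (adjusted p = 0.00111). With siNHSL1 (n = 2) the transferrin receptor gene TFRC, which takes up iron, rose from 392 ± 30.2 to 539.5 ± 35.5 CPM (adjusted p = 6.48e-05) and the ephrin receptor gene EPHA4 from 10.3 ± 0.878 to 17.9 ± 1.82 CPM (adjusted p = 4.24e-04). The metallothionein genes MT2A and MT1G, whose proteins bind metals, fell from 25.01 ± 3.60 to 14.5 ± 2.91 CPM (adjusted p = 5.87e-04) and from 10.2 ± 1.93 to 4.84 ± 0.511 CPM (adjusted p = 0.00652). GABBR1 fell with siNHSL1 as well, from 7.51 ± 1.52 to 3.43 ± 0.848 CPM (adjusted p = 0.00786), and LAMA3 rose from 9.86 ± 0.367 to 15.9 ± 3.41 CPM (adjusted p = 0.00848), against the same 3 siNTControl libraries.

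Between deletion groups, histone genes were higher in rPCE_del than in resPCE_del in 15 of 16 (15 adjusted over the list alone, median 1.59, camera adjusted p = 0.00226, and adjusted p = 0.0803 with an estimated correlation). Fatty acid synthesis genes were higher there in 13 of 17 and lower in 3 (13 and 3 adjusted over the list alone, camera adjusted p = 2.37e-05, and adjusted p = 0.0803 with an estimated correlation). Integrated stress response genes were higher in cPCE_del than in resPCE_del in 17 of 24 and lower in 2 (17 and 2 adjusted over the list alone, camera adjusted p = 0.0168, and adjusted p = 0.392 with an estimated correlation). Prostate luminal markers were higher there in 9 of 18 and lower in 3 (9 and 3 adjusted over the list alone, camera adjusted p = 0.00140, and adjusted p = 0.0738 with an estimated correlation).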
